A study of Bos taurus with 36 samples.

How the data were processed

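Liver RNA of 36 Angus heifers on 4 diets was measured on Affymetrix arrays, with 1 array per heifer and different heifers in each diet (9 Ctrl, 9 ISe, 10 OSe and 8 Mix). Per the labels, RNA was extracted with Trizol, and biotin-labelled cRNA was made for the arrays. The deposited values are log2 signals that the authors had already normalized between arrays. The sources used here name GCOS 1.2 and Partek 6.4 and do not give the method of background correction, summarization or normalization. The log2 scale was read from the values, which held no missing or negative entry and had nearly the same distribution on each array. No further normalization was applied. Animals were housed in 8 pens, and pen and scan date per animal were not used, so no block entered the model. No paired analysis was possible because each animal number occurs once.

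The 30% of probe sets with the lowest mean over the 36 arrays were left out, which kept 18412 of 26303. The cut fell at a mean log2 signal of 5.33. Of the deposited probe sets, 16571 had a single gene symbol, 9732 were unnamed and 0 had several symbols. Of 16216 symbols on the array, 15079 were current and 1000 were updated through a synonym. Among the probe sets, 104 had low identifiers that may belong to array controls, and 56 of these were tested. Another 271 had values identical to those of at least 1 other probe set, and all were kept, with 1 copy of each as an alternative. The array gives no depth of sequencing, so precision is limited by the number of arrays. The median residual SD was 0.20 on the log2 scale with 32 residual degrees of freedom.

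Limma 3.58.1 in R 4.3.3 fitted 1 linear model with the 4 diets to each probe set, with empirical Bayes moderation and a mean-variance trend. The comparisons were the 6 pairwise differences of diets, the mean of ISe, OSe and Mix minus Ctrl, Mix minus the mean of ISe and OSe, and a moderated F-test. P values were two-sided and were adjusted by Benjamini-Hochberg over all probe sets tested in a comparison, with a threshold of 0.05. Intervals are 95% intervals of the moderated differences. For named genes, exact permutation tests used every split of the animals of the compared groups, and the mean of the supplemented groups against Ctrl used 100000 permutations.

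There were 41 gene lists fixed before the data were examined, 30 of pathways and 11 of cell type markers, each with at least 4 genes tested. A gene was represented by its probe set with the highest mean, which gave 12958 genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Lists were tested on the probe sets that passed the filter on dim signals. The plan did not state this, and both filtered and unfiltered lists had been seen before the filtered form was taken. The number of members adjusted over the list alone was counted in every list and comparison: SELENOW passed in 4 comparisons, and COX7A2 and LDHB in 1 each. The 4 comparisons of SELENOW share the same 9 control arrays, so their passes are not independent of one another. No further adjustment was made over the lists and comparisons, so some passes of this kind can arise by chance.

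The genes to be named were set by a rule fixed before the data were examined. In each pairwise comparison, where fewer than 5 genes passed, the rule took the 5 with the smallest p in each direction, as values that did not pass. It took all measured selenoproteins and Se handling genes, and up to 4 members with the smallest p of each list that was called, in the direction of the list. It took in any case the member of each list with the smallest F-test p, and the 10 genes with the smallest p in the F-test and in the 2 combined comparisons. The text names a part of these genes. The restriction of this rule to 1 probe set per gene was coded, as the plan states it, after the first tables had been seen. SLC2A5 and BOLA-DQA2 each had 1 other tested probe set, with a difference of the same sign.

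Agreement between the supplemented groups was measured as Pearson's r across probe sets of their differences from Ctrl. It was set against 100 simulated draws in which residuals within groups were relabelled over all 36 animals, so that the shared controls were redrawn each time, and against 100 random splits of the controls into 4 and 5. Counts at unadjusted p under 0.05 and counts of called lists were compared with those from regroupings of the same animals, 100 splits with the real one included. The count at unadjusted p was chosen for this because 0 probe sets passed after adjustment.

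Alternatives were no filter or a filter at 50%, quantile normalization, median centring, moderation without trend or with a robust fit, array quality weights, fits of the compared groups alone, a covariate for markers of cells other than hepatocytes, the mean of all probe sets of a gene, and leaving out each animal in turn. Added after the data were examined were a fit without control animal 34, a covariate for animal number in 3 codings (linear, in 2 bins and in 4 bins), 1 copy of identical probe sets, lists without a filter, and fits of named genes without an animal far from its group. The procedure was tested on simulated data built from the arrays for Mix minus Ctrl. It called 22% of probe sets given a log2 shift of 0.25, 64% at 0.5, 96% at 1 and 100% at 1.5, with 2 unchanged probe sets called. In these data 50 probe sets were changed at each size at once, which eases the adjustment over all probe sets. Where fewer probe sets change, the shares called can be smaller. A shift of 0.1 added to the oxidative phosphorylation list had an adjusted p of 0.00288 with an estimated correlation, and 8 other lists were called at the preset correlation with no shift added, against 0 with an estimated correlation. Figures were drawn with matplotlib 3.10.9.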

Results

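Liver gene expression was measured in 36 Angus heifers on Affymetrix arrays, with 1 array per animal. The heifers had been ranked on the selenium (Se) content of a liver biopsy taken 14 days before the diets began and then assigned at random to 4 diets. The control group (Ctrl) of 9 heifers received no added Se. The inorganic group (ISe) of 9 heifers received sodium selenite, the organic group (OSe) of 10 received Se-enriched yeast, and the mixed group (Mix) of 8 received both forms at 50:50. Each supplemented heifer received 3 mg of added Se per day, and the right lobe of the liver was sampled by biopsy on day 168. The deposited log2 signals of 26303 probe sets ran from 1.44 to 14.7. Array medians lay between 6.49 and 6.58, and the mean correlation of an array with the others, taken across probe sets that are not independent replicates, lay between 0.964 and 0.980. The number of arrays limits the precision of each comparison.

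Across the 18412 probe sets tested, limma called 0 probe sets in every one of the 6 pairwise comparisons of diets, in the mean of the supplemented groups against control, in Mix against the midpoint of ISe and OSe, and in the F-test over the 4 diets. The smallest adjusted p was 0.422, in Mix minus Ctrl, and 1.00 in each of the others. At an unadjusted p under 0.05, the F-test counted 394 probe sets, or 2.14% of those tested. Without any diet difference a share of 0.05 is reached on average. Random regroupings of the same animals had a median count of 772. The median 95% interval of a log2 difference reached 0.19 to either side in ISe minus Ctrl and in OSe minus Ctrl, and 0.20 in Mix minus Ctrl. The genes named in the comparisons are those with the smallest p and the members of gene lists fixed before the data were examined, and apart from the list tests given with them, their differences are values that did not pass over all genes.

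The mean of the 3 supplemented groups minus Ctrl asks what added Se of any form did to the liver transcriptome. SELENOW (array symbol SEPW1, probe set 12752300), which encodes a small selenoprotein, was higher in supplemented heifers by 0.29 on the log2 scale, with a 95% interval of 0.16 to 0.42, a 1.22-fold difference. Its mean signal was 9.12 ± 0.18 in Ctrl (SD, n = 9), 9.41 ± 0.13 in ISe (n = 9), 9.43 ± 0.19 in OSe (n = 10) and 9.39 ± 0.15 in Mix (n = 8). All 27 supplemented heifers lay above the control mean, and 14 lay above the highest control heifer. A two-sided permutation test of the 27 supplemented against the control heifers gave p = 2e-05. Adjusted over the list alone, SELENOW was the 1 selenoprotein of 21 tested that passed, with limma adjusted p = 0.00148, and 0 passed over all genes, where the adjusted p of SELENOW was 1.00. With each of the 36 animals left out in turn, its adjusted p over the list stayed between 0.000309 and 0.00747. This adjustment does not cover the other lists and comparisons. The differences of ISe, OSe and Mix from Ctrl share the same 9 control heifers. Their SELENOW results are therefore not independent of one another or of this mean.

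The other 20 selenoproteins gave smaller or less precise differences. They were higher in 11 cases and lower in 9, with a mean log2 difference of 0.03 and a median of 0.02 (fry p = 0.348), and 17 of them had an upper 95% limit below the SELENOW difference. GPX1, the cytosolic glutathione peroxidase, differed by 0.07 (95% interval -0.12 to 0.26) and GPX4, the phospholipid hydroperoxide glutathione peroxidase, by 0.04. SELENOP, the secreted selenoprotein that carries Se from the liver, also differed by 0.04. TXNRD1 differed by -0.01, and GPX3, the plasma glutathione peroxidase, differed by 0.34 with an interval of -0.43 to 1.10, and by 0.16 without OSe animal 39. Across all 21 selenoproteins, camera gave an adjusted p of 0.102 for the list with a mean log2 difference of 0.04, and an adjusted p of 0.763 with an estimated correlation. Among 10 genes of Se handling, 5 were higher and 5 were lower, with a camera adjusted p of 0.482. The lowest of these was PSTK, a kinase in the making of selenocysteyl-tRNA, at -0.14 (interval -0.29 to 0.01), and SELENBP1 stood at 0.02.

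**Figure D1:**
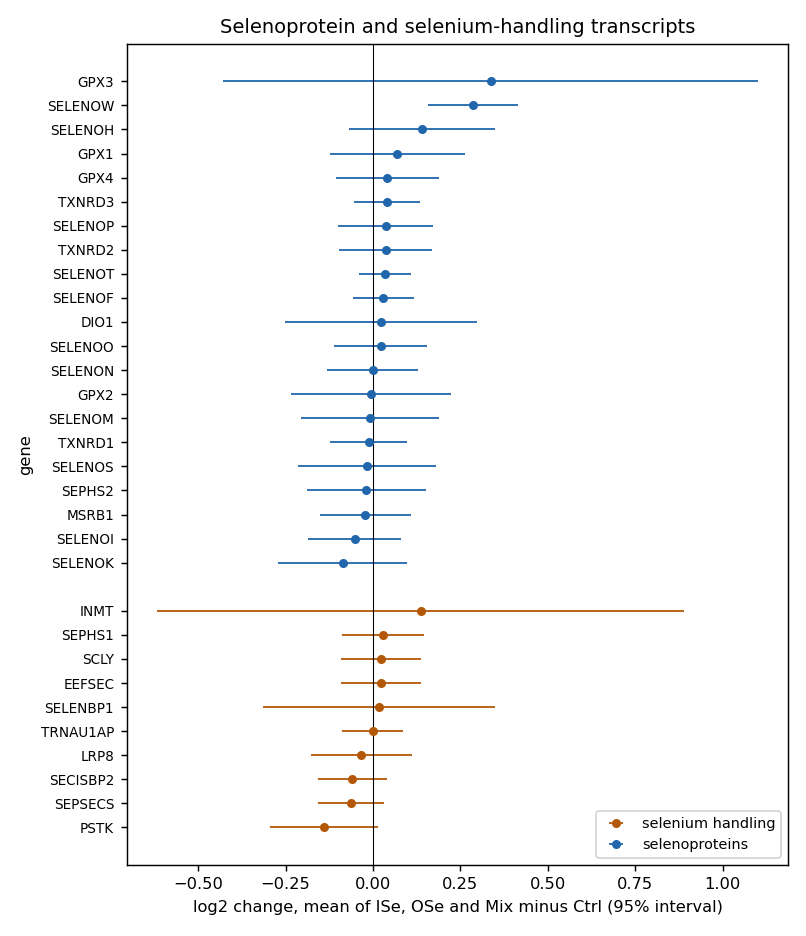
Log2 difference of the mean of the 3 supplemented groups minus Ctrl (horizontal axis) for the 21 selenoproteins and 10 Se handling genes tested. Points give the estimate and bars the 95% interval, with each list in its own colour. SELENOW stands at 0.29 with an interval of 0.16 to 0.42, and the differences of the other 20 selenoproteins lie between -0.09 and 0.34.

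**Figure D2:**
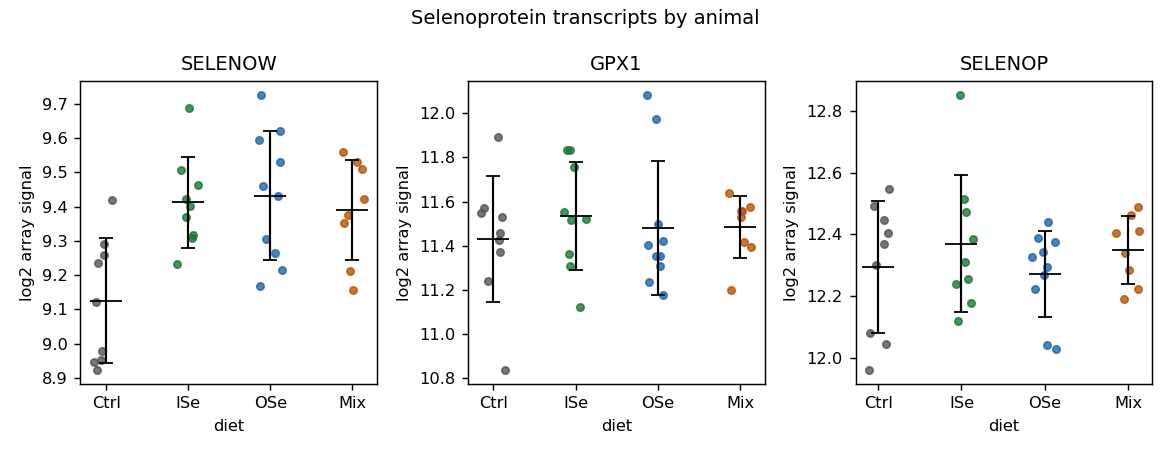
Log2 array signal (vertical axis) of SELENOW, GPX1 and SELENOP in each heifer by diet, with the group mean and SD as bars. The mean of SELENOW was 9.12 in Ctrl and between 9.39 and 9.43 in the supplemented groups.

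Outside the selenoproteins, the genes with the smallest p in this comparison were mostly higher in supplemented heifers and did not pass over all genes (limma adjusted p = 1.00). TRPC5, which encodes a cation channel, stood 0.62 higher (interval 0.32 to 0.92). Its mean signal in Ctrl lay near the cut of 5.33 for dim probe sets. The integrin subunit gene ITGA2 stood 0.32 higher, the membrane serine protease gene TMPRSS13 0.27 higher and the cadherin gene CDH4 0.25 higher. SLC2A5, the fructose transporter GLUT5, stood 1.11 higher (interval 0.41 to 1.80), and the zinc finger gene ZNF22 stood at -0.16. Of 41 lists, camera called 3 at its preset correlation of 0.01. With an estimated correlation these 3 lists had adjusted p values between 0.763 and 0.814, and 0 lists were called. The cell cycle list was higher in 22 of 24 members with a mean of 0.16, led by CCNB1 (cyclin B1) at 0.35. The oxidative phosphorylation list was lower in 58 of 76 members with a mean of -0.04, including NDUFA8 at -0.11 and UQCRH at -0.14. The skeletal muscle marker list was lower in 9 of 9 members, with a mean of -0.50 that was set by control animal 34. Random regroupings of the same animals called as many lists in 96 of 100 splits, the real one included.

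ISe minus Ctrl asks what sodium selenite did. SELENOW was 0.29 higher (interval 0.13 to 0.45), with an exact permutation p of 0.00169 and a limma adjusted p of 0.0159 over the list alone. Over the list alone it was the 1 selenoprotein that passed, and this call was lost without ISe animal 1 (limma adjusted p = 0.0543). UMOD, the gene of the kidney glycoprotein uromodulin, stood 0.24 higher, with 5.40 ± 0.07 in Ctrl (SD, n = 9) and 5.64 ± 0.11 in ISe (n = 9). These signals lay close to the cut of 5.33 for dim probe sets, so the size of the difference is not exact. The growth factor gene FGF22 stood 0.36 higher. NPY1R, a neuropeptide Y receptor gene, stood at -0.39, ZCCHC10 at -0.41, and the imprinted gene MEST at -0.56, or -0.36 without ISe animal 1. These genes did not pass over all genes (adjusted p = 1.00), and 446 probe sets had an unadjusted p under 0.05, or 2.42%.

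At the preset correlation, camera called 11 lists in ISe minus Ctrl, 5 higher and 6 lower. None of these calls held with an estimated correlation (adjusted p between 0.720 and 0.749). Cholesterol synthesis genes were higher in 20 of 21 cases with a mean of 0.07, and fatty acid synthesis genes in 13 of 16 with a mean of 0.12, among them THRSP at 0.45 and ACACA (acetyl-CoA carboxylase) at 0.29. Cell cycle genes were higher in 21 of 24 cases, with CCNB1 at 0.43. Macrophage markers had a mean of 0.07, with VSIG4 at 0.32, and B and plasma cell markers a mean of 0.21, with IGHM at 0.52. Oxidative phosphorylation genes were lower in 60 of 76 cases with a mean of -0.05, tricarboxylic acid cycle genes in 14 of 17, proteasome genes in 29 of 31 and acute phase genes in 18 of 19. Genes of growth hormone and IGF signalling were lower in 15 of 16 cases with a mean of -0.13, including SOCS2 at -0.43 and IGFBP1 at -0.61. Skeletal muscle markers had a mean of -0.51, which was 0.06 without control animal 34. Without control animal 40 the means of fatty acid synthesis genes and macrophage markers were 0.07 and 0.02, and without control animal 31 that of cholesterol synthesis genes was 0.05. The acute phase mean went from -0.12 to -0.05 and the proteasome mean from -0.05 to -0.03 without control animal 7, where neither list was called. With animal number as a covariate 4 lists were no longer called (camera adjusted p between 0.0730 and 0.286). Their means went from 0.12 to 0.07 for fatty acid synthesis, from -0.06 to -0.05 for the tricarboxylic acid cycle, from 0.07 to 0.05 for macrophage markers and from 0.21 to 0.18 for B and plasma cell markers. The count was 2 without control animal 40 and 6 without control animal 34, and 12 of 100 splits of the animals called as many lists.

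OSe minus Ctrl asks what Se-enriched yeast did. SELENOW was 0.31 higher (interval 0.15 to 0.46), with an exact permutation p of 0.00292 and a limma adjusted p of 0.00567 over the list alone, where it was the 1 selenoprotein that passed. TRPC5 stood 0.77 higher (interval 0.42 to 1.13), with 5.50 ± 0.42 in Ctrl (SD, n = 9) and 6.28 ± 0.54 in OSe (n = 10). Its Ctrl mean lay near the cut of 5.33 for dim probe sets, so the size of the difference is not exact. ITGA2 stood 0.41 higher and TMPRSS13 0.28 higher. The urea transporter gene SLC14A1 stood at -0.37 and TCEA2, a transcription elongation factor gene, at -0.33. These genes did not pass over all genes (adjusted p = 1.00), and 433 probe sets had an unadjusted p under 0.05, or 2.35%.

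Camera called 5 lists in OSe minus Ctrl at the preset correlation. With an estimated correlation the adjusted p values lay between 0.610 and 0.837, so none of the 5 held. Ribosomal protein genes were higher in 48 of 66 cases with a mean of 0.04, with RPL8 at 0.16. Genes of fatty acid oxidation and ketogenesis were lower in 18 of 22 cases with a mean of -0.07, including HADH at -0.19 and ACAA2 at -0.14. Bile acid genes were lower in 10 of 12 cases, with CYP27A1, a sterol hydroxylase, at -0.17. Interferon response genes were lower in 22 of 24 cases with a mean of -0.39, including MX1 at -0.80 (interval -1.91 to 0.31) and MX2 at -0.95. Their mean ran from -0.61 without OSe animal 39 to -0.27 without OSe animal 24. That of ribosomal protein genes was 0.01 without control animal 7, and those of fatty acid oxidation and bile acid genes were each -0.04 without OSe animal 39, where neither list was called. Skeletal muscle markers had a mean of -0.48, which was 0.09 without control animal 34, where the list was called as higher. The count was 12 without OSe animal 2 and 3 without OSe animal 25, and 97 of 100 splits called as many lists.

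Mix minus Ctrl asks what the equal mixture did. SELENOW was 0.27 higher (interval 0.10 to 0.43), with an exact permutation p of 0.00728 and a limma adjusted p of 0.0465 over the list alone, where it was the 1 selenoprotein that passed. This call rested near the threshold. Its adjustment covered 21 of the 25 selenoproteins on the array, those kept by the filter on dim probe sets. The call was not computed over all 25, so it may depend on that filter. It was lost with animal number as a covariate (adjusted p = 0.117), where the difference was 0.245. It held in 15 of 36 fits that each left out 1 animal, with adjusted p values from 0.0121 to 0.136. The difference ran from 0.240 to 0.302 in those fits. SELENOH stood 0.28 higher, with an adjusted p of 0.369 over the list. SLC2A5 had the widest difference among the named genes, at 1.59 (interval 0.71 to 2.47), with 8.32 ± 0.76 in Ctrl (SD, n = 9) and 9.91 ± 0.66 in Mix (n = 8). Its exact permutation p was 0.000576, while its limma adjusted p over all genes was 1.00. GPR55, a lipid-sensing receptor gene, stood 0.46 higher and PLAC9 0.39 higher. IDO2, an enzyme gene of tryptophan breakdown, stood at -0.53, SNAPIN at -0.26 and ZNF22 at -0.23. In all, 570 probe sets had an unadjusted p under 0.05, or 3.10%.

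At the preset correlation, camera called 6 lists in Mix minus Ctrl. Each of the 6 had an adjusted p of 0.789 with an estimated correlation, so none held. Cell cycle genes were higher in 22 of 24 cases with a mean of 0.30, including CCNB1 at 0.47, CDC20 at 0.47 and CDK1 at 0.62, and that mean ran from 0.17 without Mix animal 5 to 0.39 without Mix animal 9. Macrophage markers were higher in 12 of 14 cases, with VSIG4 at 0.36. Their mean went from 0.13 to 0.08 without control animal 40, where the list was not called. Ribosomal protein genes were lower in 56 of 66 cases with a mean of -0.07, including RPL14 at -0.11, and the mean was -0.05 without Mix animal 12. Oxidative phosphorylation genes were lower in 56 of 76 cases, with COX7A2, a subunit gene of cytochrome c oxidase, at -0.26. Complement and coagulation genes had a mean of -0.03, with PROC (protein C) at -0.17, and skeletal muscle markers a mean of -0.50, which was 0.06 without control animal 34. With animal number as a covariate the calls of the cell cycle and muscle lists stayed and the other 4 were lost (adjusted p between 0.0502 and 0.172). The mean of ribosomal protein genes went from -0.07 to -0.04, that of oxidative phosphorylation genes from -0.05 to -0.03 and that of macrophage markers from 0.13 to 0.10, while that of complement and coagulation genes stayed at -0.03. The count was 10 without control animal 17, and 62 of 100 splits called as many lists.

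OSe minus ISe compares the organic and inorganic forms at equal added Se. BOLA-DQA2 (probe set 12804650), which encodes an MHC class II alpha chain, stood 1.77 higher in OSe (interval 0.78 to 2.76), with 5.65 ± 1.32 in ISe (SD, n = 9) and 7.42 ± 0.44 in OSe (n = 10). Its exact permutation p was 0.00186 and its limma adjusted p over all genes was 1.00. All 10 OSe heifers lay at or above 6.70, and the ISe heifers lay between 4.11 and 7.76. The Ctrl heifers lay between 4.41 and 7.54 with a median of 6.80, nearer to the OSe median of 7.375 than to that of ISe. The ISe median was 5.07, below the cut of 5.33 for dim probe sets, so the size of the difference is not exact. NPY1R stood 0.44 higher in OSe and PUS7L, a gene related to pseudouridine synthases, 0.31 higher, while SAP18 stood at -0.18, PROKR1 at -0.39 and WNT2 at -0.32. SELENOW differed between the forms by 0.02 (interval -0.13 to 0.17), and 0 selenoproteins passed over the list alone. There were 529 probe sets with an unadjusted p under 0.05, or 2.87%.

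**Figure D3:**
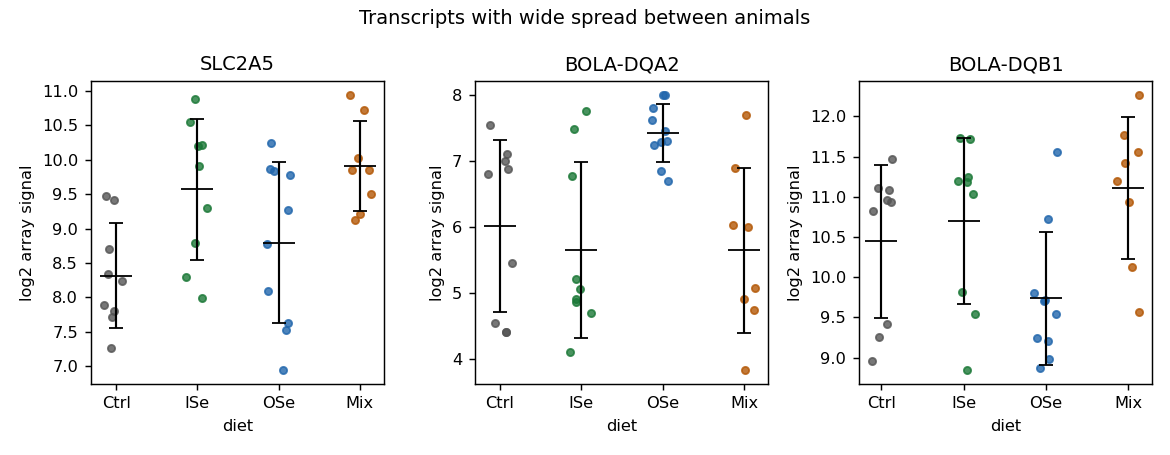
Log2 array signal (vertical axis) of SLC2A5, BOLA-DQA2 and BOLA-DQB1 in each heifer by diet, with the group mean and SD as bars. The SD of BOLA-DQA2 was 0.44 in OSe and 1.30 in Ctrl, and the mean of SLC2A5 ran from 8.32 in Ctrl to 9.91 in Mix.

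Camera called 13 lists in OSe minus ISe at the preset correlation, 4 higher and 9 lower in OSe. With an estimated correlation the adjusted p values lay between 0.772 and 0.884, so none held. Without OSe animal 39, whose array had the lowest mean correlation with the others (0.964) and the lowest array quality weight (0.469), 3 lists were called. Ribosomal protein genes were higher in 52 of 66 cases, with RPL24 at 0.17, and oxidative phosphorylation genes in 55 of 76. Acute phase genes were higher in 18 of 19 cases with a mean of 0.20 (0.12 without OSe animal 39) and a median of 0.09, and HP (haptoglobin) stood at 1.54 with an interval of -0.23 to 3.31. Genes of the unfolded protein response were higher in 21 of 23 cases, with SDF2L1 at 0.24, or 0.08 without OSe animal 39. Genes of fatty acid oxidation were lower in OSe in 19 of 22 cases with HADH at -0.24, those of fatty acid synthesis in 14 of 16 with FADS2 at -0.28, those of cholesterol synthesis in 19 of 21, and bile acid genes in 11 of 12. All 4 calls were lost without OSe animal 39, where the means went from -0.08 to -0.04, from -0.14 to -0.05, from -0.08 to -0.02 and from -0.10 to -0.06, and the FADS2 difference was -0.07. Cytochrome P450 genes were lower in 13 of 16 cases with CYP2D14 at -0.41, and urea cycle and amino acid breakdown genes in 16 of 25 with OTC (ornithine transcarbamylase) at -0.20, or -0.12 without the same animal. Interferon response genes had a mean of -0.30, which ran from -0.52 without OSe animal 39 to -0.04 without ISe animal 6. At the preset correlation this list also followed animal number, with a mean of -0.21 per 10 numbers. It did not with an estimated correlation (camera adjusted p = 0.881). The median number was 31 in OSe and 15 in ISe. With the number as a covariate the mean of the list was -0.12 (adjusted p = 0.250). Cell cycle genes had a mean of -0.14, from -0.24 without OSe animal 16 to -0.10 without OSe animal 39, and macrophage markers a mean of -0.08, from -0.12 without OSe animal 16 to -0.01 without OSe animal 25. With the covariate 4 more lists were no longer called (adjusted p between 0.0557 and 0.207), with means that went from 0.05 to 0.03 for ribosomal protein genes, from 0.04 to 0.03 for oxidative phosphorylation, from -0.14 to -0.08 for fatty acid synthesis and from -0.14 to -0.11 for the cell cycle. The count of lists was 8 without OSe animal 35, and 23 of 100 splits called as many lists.

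Mix minus ISe and Mix minus OSe compare the mixture with each form alone. Against ISe, SLITRK4 stood 0.64 higher, RGSL1 1.14 higher (interval 0.43 to 1.84) and the tetraspanin gene TSPAN5 0.27 higher, while COX7A2 stood at -0.29, RPS9 at -0.22 and the lipocalin gene LCN10 at -0.30. Against OSe, BOLA-DQA2 stood at -1.77 (interval -2.80 to -0.75), with an exact permutation p of 0.000663. BOLA-DQB1 (array symbol BLA-DQB, probe set 12806486), an MHC class II beta chain gene, stood 1.37 higher, with 9.74 ± 0.83 in OSe (SD, n = 10) and 11.1 ± 0.88 in Mix (n = 8). GPR55 stood 0.42 higher and RIN2 0.31 higher, while PUS7L stood at -0.34, GOLGA3 at -0.24 and COX7A2 at -0.31. Limma called 0 of these over all genes (adjusted p = 1.00), with 422 probe sets under an unadjusted p of 0.05 in Mix minus ISe, or 2.29%, and 642 in Mix minus OSe, or 3.49%. Adjusted over the list alone, LDHB (lactate dehydrogenase B) was the 1 glycolysis gene that passed in Mix minus OSe, at -0.44 (interval -0.70 to -0.17, limma adjusted p = 0.0227). This adjustment does not cover the other lists and comparisons, so such a pass can arise by chance. SELENOW differed by -0.02 (interval -0.19 to 0.14) from ISe and by -0.04 (interval -0.20 to 0.12) from OSe.

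Camera called 4 lists in Mix minus ISe and 7 in Mix minus OSe at the preset correlation. With an estimated correlation the adjusted p was 0.991 for the 4 lists against ISe and between 0.894 and 0.913 for the 7 against OSe, so none held. Ribosomal protein genes were lower in Mix in 50 of 66 cases against ISe and in 60 of 66 against OSe, where RPS9 and RPL24 each stood at -0.24. Cell cycle genes were higher in 22 of 24 cases against ISe and in 21 of 24 against OSe, with AURKA at 0.30 and 0.50. Endothelial markers were higher in 13 of 15 cases against ISe, with KDR at 0.09, and in 12 of 15 against OSe, with TEK at 0.15. Proteasome genes were higher in 26 of 31 cases against ISe. The ribosomal protein mean against ISe went from -0.05 to -0.03 without ISe animal 30 or Mix animal 12. Against ISe the endothelial mean went from 0.08 to 0.05 without ISe animal 30, and the proteasome mean from 0.04 to 0.02 without ISe animal 15. Each of these calls was lost in those fits. Against OSe, macrophage markers were higher in 13 of 14 cases with C1QC at 0.26 (0.17 without OSe animal 25), fatty acid synthesis genes in 13 of 16 with ELOVL6 at 0.36, and bile acid genes in 10 of 12 with CYP27A1 at 0.22, while unfolded protein response genes were lower in 21 of 23. Without OSe animal 39, the array with the lowest weight, the calls of 4 lists against OSe were lost. Their means went from 0.18 to 0.08 for fatty acid synthesis, from 0.06 to 0.02 for bile acids, from -0.10 to -0.04 for the unfolded protein response and from 0.07 to 0.05 for endothelial markers. The macrophage mean went from 0.13 to 0.07 without OSe animal 25, where it was not called. The cell cycle mean against ISe was 0.15 and fell to 0.01 without Mix animal 5, and against OSe it fell from 0.29 to 0.15. With animal number as a covariate the fatty acid synthesis and bile acid lists were no longer called against OSe (adjusted p = 0.298 and 0.0981), with means of 0.10 and 0.03. The count against ISe was 1 without ISe animal 30 and that against OSe was 12 without Mix animal 13, and 79 and 78 of 100 splits called as many lists.

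Mix minus the mean of ISe and OSe asks whether the mixture departed from the midpoint of its 2 forms. COX7A2 stood at -0.30 (interval -0.45 to -0.15), with a mean of 9.58 in Mix against 9.86 in ISe and 9.88 in OSe. It was the 1 oxidative phosphorylation gene that passed when adjusted over the list alone (limma adjusted p = 0.0237), and it did not pass over all genes (adjusted p = 1.00). The adjustment over a list leaves out the other lists and comparisons, so this pass can be a chance result. RPS9 stood at -0.23, the translation elongation factor gene EEF2 at -0.18 and LCN10 at -0.32, while GPR55 stood at 0.38, the phospholipase gene DDHD1 at 0.31 and TSPAN5 at 0.25. There were 530 probe sets with an unadjusted p under 0.05, or 2.88%. Camera called 4 lists at the preset correlation, and each had an adjusted p of 0.918 with an estimated correlation, so none held. They were ribosomal protein genes, lower in 60 of 66 cases with a mean of -0.08, and cell cycle genes, endothelial markers and macrophage markers, higher with means of 0.22, 0.08 and 0.10. Without Mix animal 5 the cell cycle mean was 0.08 and was not called, and the macrophage mean was 0.06. The macrophage call held in 26 of 36 fits that each left out 1 animal, and it was lost with animal number as a covariate, at a mean of 0.08 (adjusted p = 0.165). The count was 2 without Mix animal 5 and 7 without Mix animal 12, and 97 of 100 splits called as many lists.

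The log2 differences of the 3 supplemented groups from Ctrl were compared with one another across the 18412 probe sets, which are not independent replicates. Pearson's r was 0.456 for ISe and OSe, 0.527 for ISe and Mix, and 0.426 for OSe and Mix. Because the 3 differences share the same control animals, groups simulated without any diet difference gave mean r values of 0.524, 0.481 and 0.506, with ranges of 0.178 to 0.704, 0.168 to 0.715 and 0.194 to 0.781, and each observed r lay inside its range. With the controls split at random so that no control animal was shared, the mean r was -0.107, -0.038 and -0.097.

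Control animal 34 stood apart in skeletal muscle transcripts. Its log2 signal was 12.5 for MB (myoglobin), 12.3 for TTN (titin), 12.4 for ACTA1 (skeletal actin) and 11.6 for CKM (muscle creatine kinase), where the means of the other 35 heifers were 5.27, 5.14, 6.30 and 5.58. Without this animal the mean log2 difference of the 9 muscle markers between supplemented and control heifers was 0.07, where it was -0.50 with it. At the preset correlation the list was then called as higher in supplemented heifers. The fit without this animal was not run with an estimated correlation. With all 36 animals and an estimated correlation, 0 of the 41 lists were called in any comparison, the 11 lists of cell type markers included. The SELENOW difference was 0.29 without this animal, with a limma adjusted p of 0.00336 over the list alone.

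**Figure D4:**
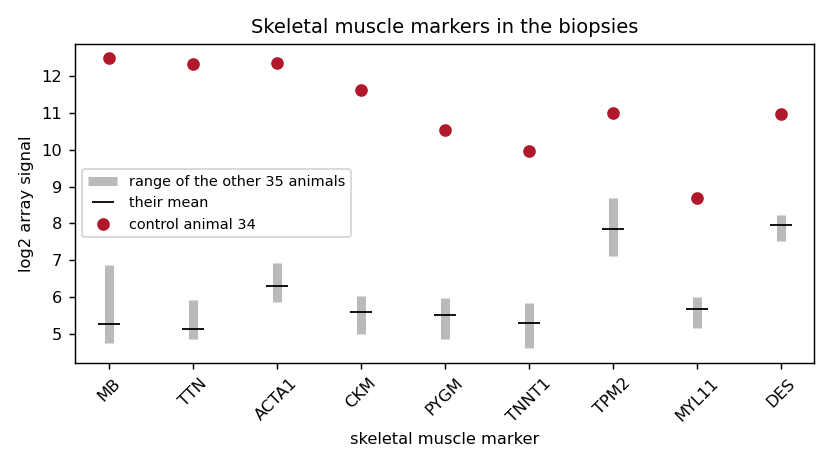
Log2 array signal (vertical axis) of the 9 skeletal muscle markers tested in control animal 34 (points) and the range of the other 35 heifers (bars). MB stands at 12.5 in animal 34 and at no more than 6.86 in the others.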

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

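The tests of a single animal behind the SELENOW difference, of muscle tissue in 1 biopsy and of both explanations for BOLA-DQA2 were chosen after the result was seen. SELENOW was higher in supplemented than in control heifers by 0.29 on the log2 scale and passed over its list alone. Array medians of the already normalized values lay between 6.49 and 6.58, a range narrower than this difference. Median centring could therefore not bring the SELENOW difference near 0, and its outcome was fixed in advance. The lower 95% limit stayed at 0.153 or above after quantile normalization and after median centring. A difference in overall level before the authors normalized the arrays cannot be judged from these values. The order of the animals, with animal number as a stand-in, is argued against by a lower limit of 0.144 with that number as a covariate, and a single animal by a lowest limit of 0.127 over the 36 fits that each left out 1. Se supply may act on selenoprotein transcripts together, and this stays open, because the other selenoproteins had a mean log2 difference of 0.029 with a fry p of 0.348. An action of Se on SELENOW alone remains a hypothesis that was not tested further.

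Skeletal muscle markers were lower in supplemented heifers, with a mean of -0.50 over 9 markers. Control animal 34 lay far from the rest of its group for MB (12.48, where the next control stood at 5.69), TTN (12.33), ACTA1 (12.35) and CKM (11.62). Skeletal muscle tissue taken with this biopsy may account for the pattern, since the mean difference was 0.069 without the animal. All 9 markers stood above the range of the other 35 heifers in it, among them PYGM at 10.5 and TNNT1 at 9.96. Of 19 markers in the list 9 were tested, and DES among them is also on the list of stellate cell markers. A diet effect, the biological alternative, would need the lower level to stay without this animal. At the preset correlation camera then called the list as higher in OSe minus Ctrl and for the supplemented mean. Its calls in ISe minus Ctrl and in Mix minus Ctrl were lost.

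BOLA-DQA2 stood higher in OSe than in ISe and in Mix, by 1.77 in each case, and did not pass over all genes. Its median was 6.80 in Ctrl (range 4.41 to 7.54), 7.375 in OSe and 5.54 in Mix. By median, Ctrl stood nearer to OSe than to ISe or Mix. The median of BOLA-DQA2 in ISe was 5.07 and its lowest signal in Mix 3.84, below the cut of 5.33 for dim probe sets. The size of the difference is therefore not exact. Different amounts of antigen-presenting cells in the biopsies are argued against, since their transcripts CD74 and BOLA-DRA did not stand higher in OSe. The mean of both was -0.15 in OSe minus ISe and -0.18 in OSe minus Mix, with upper 95% limits of no more than 0.053, below the lower limit of 0.75 for BOLA-DQA2. This comparison between groups replaced an earlier test of the relation within groups, whose upper 95% limit was 0.458 and which does not decide the point. Inherited differences between animals in the MHC class II region, including sequence differences under the probes, may contribute and stay open. The relation within groups of BOLA-DQA2 and BOLA-DQB1 had an r of -0.295 (95% interval -0.580 to 0.054). Its permutation p was 0.109, and 0.218 after adjustment over 2 relations. No genotypes were analysed here. Diet as the cause cannot be told apart from such differences by the expression values alone.

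Other values were far from the rest of their group, among 336 pairs of a named gene and a group tested, where 25 stood out (7.44%) and chance alone gives about 1 in 20. OSe animal 39 stood out for GPX3 (12.41, next 7.96), FADS2 (11.56), OTC (10.37), SDF2L1 (8.957) and UQCRH (8.197). OSe animal 25 stood out for C1QC (10.22) and PROC (10.76), and OSe animal 35 for MB (6.858) and TTN (5.922). Mix animal 5 stood out for GPX3 (8.786), HP (11.43) and CKM (5.002), Mix animal 13 for LCN10 (5.165) and SELENOO (7.682), and Mix animal 11 for PROC (11.1). In ISe, animal 1 stood out for MEST (5.719), animal 6 for DIO1 (11.12), animal 10 for CDH4 (6.456) and animal 30 for ACAA2 (12.67). In Ctrl, animal 7 stood out for DIO1 (10.35) and animal 40 for FADS2 (13.31).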

How the results depend on the processing

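The fits of single genes without an animal far from its group, the fit without control animal 34, the covariates for animal number, the single copies of identical probe sets and the lists without a filter were chosen after the data were examined. The count of probe sets called stayed at 0 in each comparison and in the F-test under each alternative run, the fits without 1 animal included. The alternative offsets before taking logs were not run, since the values were already on a log2 scale. This covers the fit without a filter on dim probe sets. The SELENOW difference between supplemented and control heifers passed over the list alone in each of the 9 settings in which it was computed, with adjusted p between 0.00031 and 0.00336. None of these settings lifted the filter on dim probe sets for the list. In Mix minus Ctrl its call was lost with median centring (adjusted p = 0.0521), without a trend (0.0525), with the covariate for markers of cells other than hepatocytes (0.0656), with animal number as a covariate (0.117) and without animal 34 (0.0694), within a range of 0.0132 to 0.117 over the settings. The difference itself moved little, from 0.245 with animal number to 0.292 with array quality weights. In ISe minus Ctrl the call was lost without ISe animal 1 (0.0543), where the difference was 0.253.

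The number of lists called at the preset correlation moved most. With an estimated correlation and with fry it was 0 in each of the 8 comparisons. With array quality weights it was 5 in ISe minus Ctrl, 3 in OSe minus Ctrl and 6 for the mean of the supplemented groups minus Ctrl. With animal number as a covariate it was 7 in ISe minus Ctrl and 5 for the supplemented mean. Without animal 34 it was 6 in both. Without a filter it was 8 for the supplemented mean, and with the covariate for markers of other cells it was 9 pathway lists in Mix minus OSe, where 5 were called without the covariate. The cause was not tested. Leaving out each animal in turn gave 2 to 13 lists in ISe minus Ctrl (2 without Ctrl 40, 6 without Ctrl 34, 7 without ISe 6 or ISe 42), 3 to 12 in OSe minus Ctrl (3 without OSe 25, 8 without OSe 29, 11 without OSe 24 or OSe 33, 12 without OSe 2), and 4 to 10 in Mix minus Ctrl (10 without Ctrl 17). It gave 3 to 14 in OSe minus ISe (3 without OSe 39, 8 without OSe 35), 1 to 5 in Mix minus ISe (1 without ISe 30, 2 without ISe 3, ISe 10 or ISe 42), 5 to 12 in Mix minus OSe (11 without OSe 2, 12 without Mix 12 or Mix 13) and 2 to 7 in Mix minus the midpoint (2 without Mix 5, 7 without Mix 12). For the supplemented mean it gave 3 to 12, with 12 without Ctrl 17 or OSe 35. The correlation of differences with controls split was -0.107 for ISe and OSe, -0.038 for ISe and Mix, and -0.097 for OSe and Mix, since no control animal was then shared.

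Some differences near 0 for the supplemented mean minus Ctrl changed sign. With quantile normalization SELENON stood at 0.0084 and TRNAU1AP at 0.0088. With array weights DIO1 stood at -0.013 and TRNAU1AP at 0.0024, and with the covariate for other cells TRNAU1AP at 0.00010. With animal number SEPHS2 stood at 0.022 and EEFSEC at -0.0065. With animal number in 4 bins GPX2 stood at 0.00090, SELENOO at -0.0039, SEPHS2 at 0.055 and EEFSEC at -0.025. The cause was not tested. Without Ctrl animal 7 DIO1 stood at -0.147, and without ISe animal 6 at 0.049. Without animal 34, whose muscle transcripts set these values, the muscle list stood at 0.057 in ISe, 0.086 in OSe and 0.063 in Mix, each minus Ctrl, and at 0.069 for the supplemented mean. ACTA1 then stood at 0.0039 in OSe minus Ctrl and 0.0028 for the supplemented mean, MB at 0.051 in OSe and 0.0040 in Mix, CKM at 0.018 for the supplemented mean, and TTN at 0.12 in OSe, 0.042 in Mix and 0.044 for the supplemented mean. Counts at unadjusted p under 0.05 moved by over 1.5 times from those in the report under 4 settings. Without a filter 26303 probe sets were tested, and with 50% left out fewer than the 18412 of the report. The number tested changes such counts, so under these filters they are not a like comparison. It does not account for all of the moves, whose further cause was not tested. The counts listed for these filters each rose or fell by a larger factor than the number tested. Without a filter they were 861 in ISe minus Ctrl, 740 in OSe minus Ctrl, 918 in Mix minus Ctrl, 860 in OSe minus ISe, 781 in Mix minus ISe, 821 for the supplemented mean and 853 for Mix minus the midpoint. With 50% left out they were 214 in ISe minus Ctrl, 275 in OSe minus Ctrl, 225 in Mix minus ISe, 234 for the supplemented mean and 331 for Mix minus the midpoint. With animal number in 2 bins they were 720 in Mix minus ISe and 895 for Mix minus the midpoint, and with 4 bins 914 in Mix minus Ctrl, 1253 in Mix minus OSe and 1022 for Mix minus the midpoint. The cause of the moves with bins was not tested.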

Other observations

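The relations with animal number in this part were examined only after the first principal component was seen to follow the number, and the count at unadjusted p used for the splits was chosen after 0 probe sets passed. Antioxidant and Se-linked metabolism outside the selenoproteins gave small mean log2 differences between supplemented and control heifers. The list of NRF2 targets had a mean of 0.01 (camera adjusted p = 0.584), other antioxidants 0.03 (0.629), glutathione S-transferases -0.03 (0.280) and conjugation enzymes 0.01 (0.629). Genes of methionine, transsulfuration and one-carbon metabolism were lower in 15 of 20 cases with a mean of -0.04 (0.0738), and genes of gluconeogenesis and glycogen were lower in 12 of 14 with a mean of -0.06 (0.0804). Glycolysis genes had a mean of -0.02 (0.597), MHC and antigen presentation genes -0.01 (0.597), heat shock genes 0.03 (0.459), immediate early genes -0.01 (0.629), circadian clock genes -0.06 (0.200) and iron and heme genes -0.01 (0.935).

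Cell type markers that were called in none of the comparisons had small means for the same difference. Hepatocyte markers stood at -0.02 (camera adjusted p = 0.271), cholangiocyte markers at 0.05 (0.223), stellate cell and fibroblast markers at 0.02 (0.348), and T and NK cell markers at -0.05 (0.482). Erythroid markers stood at 0.05 (0.647), neutrophil and platelet markers at 0.03 (0.482) and adipose markers at 0.03 (0.629).

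The first principal component, with 11.9% of the variance, was related to animal number across the 36 heifers, with Pearson's r of 0.540 (permutation p = 0.00064, adjusted p = 0.00384 over 6 components) and Spearman's rho of 0.644 (permutation p = 6e-05). Without the 2 animals farthest from the median number, r was 0.518. The second component had an r of 0.420 (permutation p = 0.0109, adjusted p = 0.0326), a rho of 0.379 (permutation p = 0.0237, adjusted p = 0.0677) and an r of 0.427 without the 2 farthest animals. The fifth had an r of 0.382 (permutation p = 0.0218, adjusted p = 0.0436), a rho of 0.357 (permutation p = 0.0339, adjusted p = 0.0677) and an r of 0.394 without them. A test of diet on the first component gave a permutation p of 0.973. With diet in the model, limma called 922 probe sets along animal number, 533 higher and 389 lower, with 3989 at an unadjusted p under 0.05. GOLGA7 (-0.14 per 10 numbers), ATP5PD (0.09) and STRN (0.11) had the smallest p. At the preset correlation, camera called 7 lists along animal number, and 0 were called with an estimated correlation. The means per 10 numbers were -0.21 for interferon response genes, -0.07 for MHC and antigen presentation, -0.07 for fatty acid synthesis, 0.03 for ribosomal protein genes, 0.01 for oxidative phosphorylation, 0.01 for the proteasome and 0.01 for hepatocyte markers. The median number was 31 in Ctrl, 15 in ISe, 31 in OSe and 12.5 in Mix. The sources used here do not say what the number follows.

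The counts were compared with those from 100 splits of the same animals, the real one included, and chance was not excluded for any of them. As many probe sets at unadjusted p under 0.05 were found in 90 splits for ISe minus Ctrl (446 real, 2902 in the highest other), 96 for OSe minus Ctrl (433, 2155), 65 for Mix minus Ctrl (570, 1816), 92 for OSe minus ISe (529, 2290), 90 for Mix minus ISe (422, 2426) and 87 for Mix minus OSe (642, 1979). The numbers were 95 for the supplemented mean (448, 1732), 95 for Mix minus the midpoint (530, 2199) and 100 for the F-test (394, 1972). Each real count of probe sets lay below the median of its other splits, as for the F-test (394 against 772). As many lists at the preset correlation were called in 12 splits for ISe minus Ctrl (11 real, 17 in the highest other), 97 for OSe minus Ctrl (5, 19), 62 for Mix minus Ctrl (6, 17), 23 for OSe minus ISe (13, 19), 79 for Mix minus ISe (4, 16) and 78 for Mix minus OSe (7, 19). They were called in 96 for the supplemented mean (3, 19) and 97 for Mix minus the midpoint (4, 20). Why some splits had several times the real count was not tested.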
